A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

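Barcode microarrays were read for pools of Saccharomyces cerevisiae DAmP strains. In a DAmP strain a resistance cassette follows the coding sequence of an essential gene. The mRNA has an extended 3' end that carries the strain's molecular barcode. The pool was crossed with a deletion of YEL068C, the reference, or of NAM7 (UPF1) or NMD2 (UPF2), which encode factors of nonsense-mediated mRNA decay. Per the labels' protocols, the haploid strains carrying both alleles were grown for 18 generations under selection and RNA was reverse transcribed from an oligonucleotide specific for the DAmP extension. Barcodes amplified from RNA (Cy3) and from genomic DNA of another aliquot (Cy5) were hybridised together. The dyes were not swapped.

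The series holds 6 arrays, 2 per pool. The series text calls the second array of each pool a technical replicate begun from the raw cell material, so p-values measure only the technical spread between arrays of 1 cross per deletion.

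The authors deposited one table of processed values with 15743 probe rows. The authors made the deposited values, read here as log2 ratios, from the barcode signals of both dyes, per the labels' protocols. The deposited table states neither the base of the logarithm nor the numerator, and base 2 was inferred from the range of the values, so folds depend on that base. A value was present for 843 probes on at least 1 array and for 527 on all 6. Each deposited column has a median of 0, and the scaling behind it is not given in the sources used here. Scanner intensities, background and saturation were not analysed here, and the precision stated rests on the spread between arrays alone. The series text limits interpretation to up tags. Up and down tags could not be told apart here, and all probes with values were used.

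The platform table given for this work named 1 gene for 827 of the 843 probes, several genes for 0 and none for 16. Probes valued on all 6 arrays were averaged per gene, which left 444 features, 433 named genes and 11 unnamed probes. Of these, 83 had 2 probes, whose values differed by a median of 0.06 and in 98.4% of cases by less than 0.2. Each array was centred on its median over these features.

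The direction of the ratio was tested on a list of abundantly expressed genes fixed in advance. In the deposited sign, its 15 measured members had a median of -2.19 in the YEL068C pool and 14 lay below 0 (permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). The deposited value is therefore likely DNA over RNA, Cy5 over Cy3, and its sign was turned so that a positive value means more RNA per DNA. If the direction were the other one, every increase given here would be a decrease, and the highest ratios would be the lowest.

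Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg threshold 0.05) over all 6 arrays with 1 term per pool, which leaves 3 residual degrees of freedom. Comparisons were NMD2 against YEL068C, NAM7 against YEL068C, the mean of both against YEL068C, and NMD2 against NAM7. Arrays with the same replicate number deviated together. The correlations of the replicate deviations between pools were 0.89, 0.85 and 0.89, all over the limit set for treating numbers as pairs, a decision taken before calls were compared. The main fit, fixed in advance, has no term for the number, so the spread between numbers enters its error. The typical SD was 0.297 in it and 0.147 with the number as a block. A count of 0 from the main fit therefore does not show that no gene changed. The first principal component (51.5% of the variance) separated the arrays by replicate number and the next (40.1%) separated YEL068C from both mutant pools. The numbers come from the sample titles, which do not say what the arrays of one number shared. Values with the replicate number as a block, and within each set of same-numbered arrays, are given where they change a call.

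Gene lists, 18 in number with 858 entries, were fixed before the data were examined, as were the pool assignments and the rule for named genes. The tests not named as chosen later and the alternatives not named as added were fixed then too. Lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. Camera compares a list with the other genes, whereas fry tests whether its genes move, on balance, one way. Genes were named by rule: up to 12 largest increases and 12 largest decreases among genes passing the threshold with arrays that do not overlap, with up to 5 each way for NMD2 against NAM7. Where no gene of a comparison passed, the 10 smallest p-values in either direction were taken. The rule also took up to 4 passing members per list (or the 2 smallest p-values), the 4 longest and 4 shortest genes, and the 5 highest and 5 lowest ratios in the YEL068C pool. Genes outside the rule are named as such.

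Coding length was the gene span of RefSeq assembly R64, matched for 97.5% of features. Spans of 96.3% of its 6021 protein-coding genes are multiples of 3, so they hold no untranslated regions, although introns are included. The build behind the platform is not given in the sources used here, and the assembly served only for names, lengths and neighbours. Trends with coding length are Spearman correlations across genes, which are not independent replicates, with 100000 permutations. Class medians have 95% bootstrap intervals over genes (10000 resamples).

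The fits were tested on simulated data with 200 of 444 genes changed and with the replicate-number differences of the real arrays, over 20 draws. For the mean contrast, the fit without the block called 3.02% of genes changed by 0.5 (log2), 57.7% changed by 1 and 95% changed by 2, and 0% of its calls were unchanged genes. With the block these shares were 90.1%, 100% and 100%, and 3.64% of the calls were unchanged genes. Every simulated pool had the same replicate-number difference, averaged over pools, and independent noise with the spread of the blocked fit. That is the model the block assumes, so these shares do not test the block on the real arrays. There, the replicate deviations correlated between pools with 0.85 to 0.89 only. A simulated list shift of 0.5 was called in 20 of 20 draws for this contrast, with 3 calls of other lists over these draws, and 0 lists were called in 20 draws without a shift. The list simulation drew the noise of each gene independently, with the spread of the blocked fit, and shifted lipid and glycan genes only. It therefore does not test lists whose genes move together. Alternatives covered centring, quantile normalization, the block, each array left out, noisy probes, missing values, the variance prior, a 1.5-fold minimum and genes within 100 kb of a deleted locus. Not every alternative was run for every result. Figures were drawn with matplotlib 3.10.9.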

Results

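The relative RNA level of extended DAmP mRNAs was measured in 3 strain pools of Saccharomyces cerevisiae, 1 carrying a deletion of YEL068C (the reference) and the others a deletion of NAM7 or NMD2. Each value is the log2 ratio of a strain's barcode in RNA to the same barcode in genomic DNA, centred on the array median, with 2 technical arrays per pool. The arrays gave a value for 660 and 749 probes in the YEL068C pool, 666 and 792 in the NAM7 pool and 658 and 798 in the NMD2 pool, and 444 features valued on all 6 arrays were compared. The ratio is likely oriented RNA over DNA, a direction taken from a preset list of abundant mRNAs rather than from the labels. None of the 6 genes of the list of decay factors and deleted loci had a value, so the deletions could not be checked on their own probes. Genes lacking values gave another view of the labels. Of 4 genes valued in the other pools and missing on both NAM7 arrays, PDS5, SEC14 and UTP15 lay within 100 kb of NAM7. Of 4 missing on both NMD2 arrays, MED6, QNS1 and SAM35 lay within 100 kb of NMD2. Among genes valued in all pools, 4 of 436 and 5 of 436 lay that close (Fisher's exact test, two-sided, p = 9.86e-06 and p = 1.57e-05). Of 30 genes missing on both YEL068C arrays, 0 lay within 100 kb of YEL068C, against 2 of 436 (p = 1 in the same exact test), so this gave no check of the YEL068C label.

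In the YEL068C pool the highest ratios belonged to RPB10, a subunit shared by the nuclear RNA polymerases (5.41 ± 0.32, SD, n = 2), and ILV5 of branched-chain amino acid synthesis (4.99 ± 0.45). Next came the pyruvate kinase gene CDC19 (4.96 ± 0.84), the histone gene HTB1 (4.24 ± 0.55) and the ribosomal protein gene RPL17A (4.22 ± 1.35). The lowest belonged to GPI15 (-3.76 ± 0.85) and KEI1 (-3.02 ± 0.86), which act in glycolipid synthesis, the primase subunit gene PRI2 (-3.65 ± 0.21), HYM1 (-2.53 ± 0.23) and FAD1 (-2.40 ± 0.61). The preset list of abundant mRNAs had a median of 2.19 over 15 genes, 14 of them above the array median (permutation p = 1e-05, two-sided, adjusted 8.5e-05 over 17 lists). The direction of the ratio was taken from this list, so its sign here is not independent evidence. With the other direction the genes named here as highest would be the lowest and the reverse. The 2 arrays of a pool correlated across genes with r = 0.90 in the YEL068C and NAM7 pools and 0.91 in the NMD2 pool, whereas NAM7 and NMD2 arrays of the same number correlated with r = 0.98 and 0.99.

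The comparison of both mutant pools with the reference asks which extended mRNAs change in relative level when nonsense-mediated decay is lost. The actin-binding profilin gene PFY1 rose by 2.05 (SE 0.25, n = 4 against 2 arrays), the mitochondrial protein gene MMF1 by 1.82 (SE 0.30), the inorganic pyrophosphatase gene IPP1 by 1.66 (SE 0.20) and the SUMO-conjugating enzyme gene UBC9 by 1.63 (SE 0.25) on the log2 scale. The SNARE gene YKT6 (1.59), the deoxyhypusine synthase gene DYS1 (1.38) and PTI1 of the 3'-end processing machinery (1.36) rose as well. DYS1 lies within 100 kb of the deleted NMD2, and whether this linkage affects its value in the NMD2 pool was not tested. Further increases were those of the tyrosyl-tRNA synthetase gene TYS1 (1.16), the squalene epoxidase gene ERG1 (1.11), the mannose-6-phosphate isomerase gene PMI40 (1.10), the mitochondrial ferredoxin gene YAH1 (1.07) and POL30, which encodes the replication clamp PCNA (0.99). OLE1, the fatty acid desaturase gene, fell by 1.69 (SE 0.26), and RPC17 of RNA polymerase III fell by 1.34 (SE 0.24). ARP2 of the actin-nucleating complex, the condensin gene BRN1, the initiation factor gene SUI3 and POL2, the DNA polymerase epsilon gene, changed by -1.16, -1.11, -1.03 and -0.99. These 12 increases and 6 decreases were the genes past the threshold (limma, smallest adjusted p = 0.0291, with 118 genes at an unadjusted p under 0.05). All mutant arrays lay on one side of both YEL068C arrays for each of them, as they did for 186 genes (41.9%). Exchangeable arrays would give 13.3%. Same-numbered arrays deviated together and the arrays of a pool come from 1 cross, so 13.3% is not the chance rate here. Within the set of arrays numbered 1, the increases ranged from 0.87 to 1.66 and the decreases from -1.51 to -0.90, and within the set numbered 2 from 1.09 to 2.43 and from -1.86 to -0.94. With the replicate block, which lowered the median SE from 0.253 to 0.124, 266 genes passed, 132 higher and 134 lower. These included all 18. Higher and lower are relative to the array median, so the near balance of the 2 counts gives no absolute direction. Without the block, 0 genes passed when either YEL068C array or either NMD2 array was left out, when arrays were not centred (which moved the median of all genes by -0.12) or when genes valued on at least 1 array per pool were tested. Without NAM7 replicate 1 or 2, 5 and 9 genes passed.

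**Figure D1:**
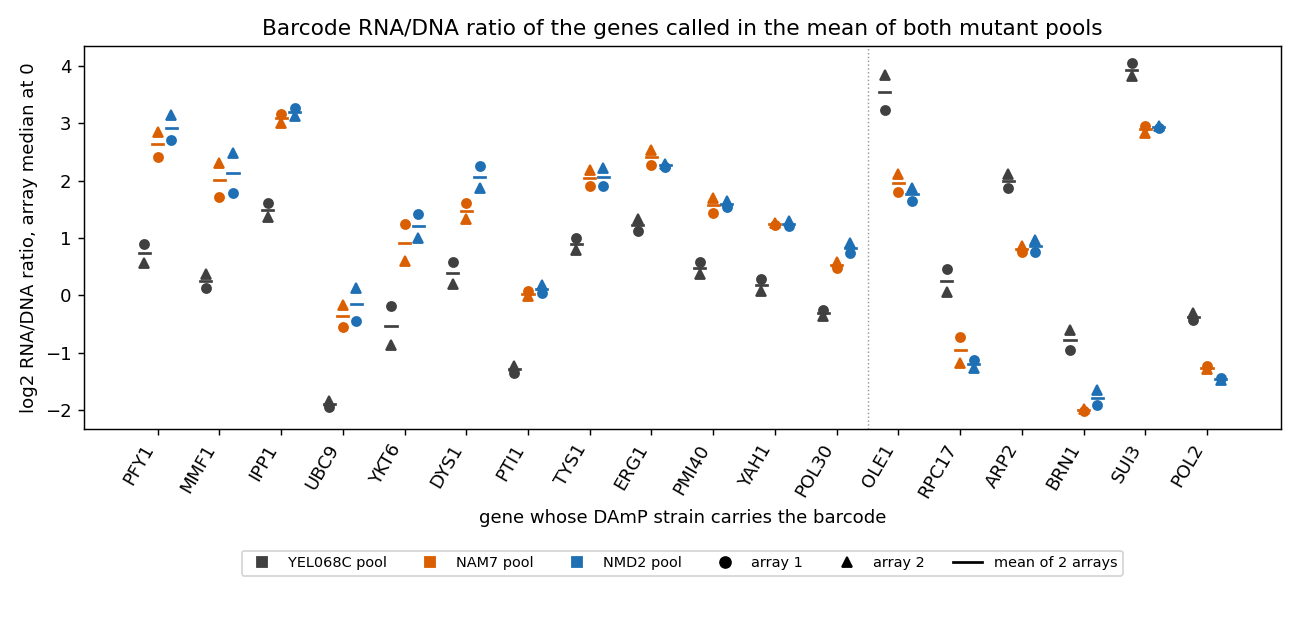
Log2 RNA/DNA ratio (vertical axis, array median at 0) of the 18 genes past the threshold in the mean of both mutant pools, by gene; circles and triangles are arrays 1 and 2 and short lines the mean of 2 arrays. All 4 mutant arrays lie above both YEL068C arrays for the 12 genes left of the dotted line and below them for the 6 genes on its right.

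Taken one pool at a time, the same contrast gave similar sizes for these genes but, over all genes, no call without the block. In the NMD2 pool the smallest p-values belonged to PFY1, IPP1, PTI1, DYS1, OLE1, UBC9, MMF1, RPC17, POL30 and POL2, and in the NAM7 pool to IPP1, PFY1, PTI1, OLE1, UBC9, MMF1, ARP2, ERG1, BRN1 and YAH1. IPP1, for example, differed from the reference by 1.60 in the NAM7 pool (SE 0.23, adjusted p = 0.099 in limma) and 1.71 in the NMD2 pool. By limma without the block 0 genes passed in either pool, with 99 genes at an unadjusted p under 0.05 in the NMD2 pool (smallest adjusted p = 0.0533) and 91 in the NAM7 pool (smallest adjusted p = 0.099). Among the 384 genes whose 2 arrays differed by at most 1 in every pool, 49 and 50 passed without it, and 85 in the mean. This filter selects on the spread that the test itself uses, so these calls are not independent evidence. With the block 239 genes passed in the NMD2 pool (126 higher, 113 lower) and 225 in the NAM7 pool (114 higher, 111 lower), among them IPP1 with adjusted p = 1.98e-06 and 7.88e-06. Leaving out NMD2 replicate 1 or 2 reduced the blocked NMD2 count to 130 and 124.

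The study is known to have asked how coding length relates to the decay of extended mRNAs. Short genes gained and long genes lost relative RNA in both mutant pools. Genes over 500 and up to 1000 nucleotides had a median change of 0.43 in the mean of both pools (95% interval 0.28 to 0.59, 106 genes), and those up to 1500 nucleotides 0.25 (0.15 to 0.35, 109 genes). The median was -0.11 for the next class, up to 2000 nucleotides (80 genes), -0.34 up to 3000 (76 genes) and -0.60 for genes over 3000 (-0.71 to -0.51, 52 genes). With the replicate block, 59 of the 106 genes over 500 and up to 1000 nucleotides rose and 9 fell, while 0 of the 52 longest rose and 45 fell. Each array was centred on its own median, so these rises and falls are relative to the other genes. Whether the long extended mRNAs fell in absolute level cannot be told. The 4 longest genes were MDN1 (14733 nucleotides, -0.86), which encodes a ribosome assembly ATPase, the RAS regulator gene IRA1 (-0.71), the small-subunit processome gene UTP20 (-0.84) and the checkpoint kinase gene MEC1 (-0.84). Over all genes, each passed with the block and not without it. The 4 shortest went both ways with the block, RPB10 (213 nucleotides, -0.64) and ACP1 (-0.73) being lower and HTB1 (0.46) and YAE1 (0.76) higher, and did not pass without it. After the same filter on array spread, which lowers the error of the test and leaves the changes as they were, MDN1, UTP20, MEC1 and YAE1 passed without the block (adjusted p = 0.0171, 0.0203, 0.0375 and 0.0403 in limma). The class up to 500 nucleotides holds 10 genes with an interval of -0.64 to 0.76. Across 433 genes Spearman's rho between change and coding length was -0.59 in the NMD2 pool, -0.62 in the NAM7 pool and -0.62 for their mean (permutation p = 1e-05 each, the smallest possible, adjusted 1.33e-05 over 4 relations). For the mean, rho was -0.57 in arrays numbered 1 and -0.62 in arrays numbered 2. Within the YEL068C pool the difference between its 2 arrays also correlated with coding length (rho = -0.29), as it did in the NAM7 pool (-0.17) and the NMD2 pool (-0.15).

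**Figure D2:**
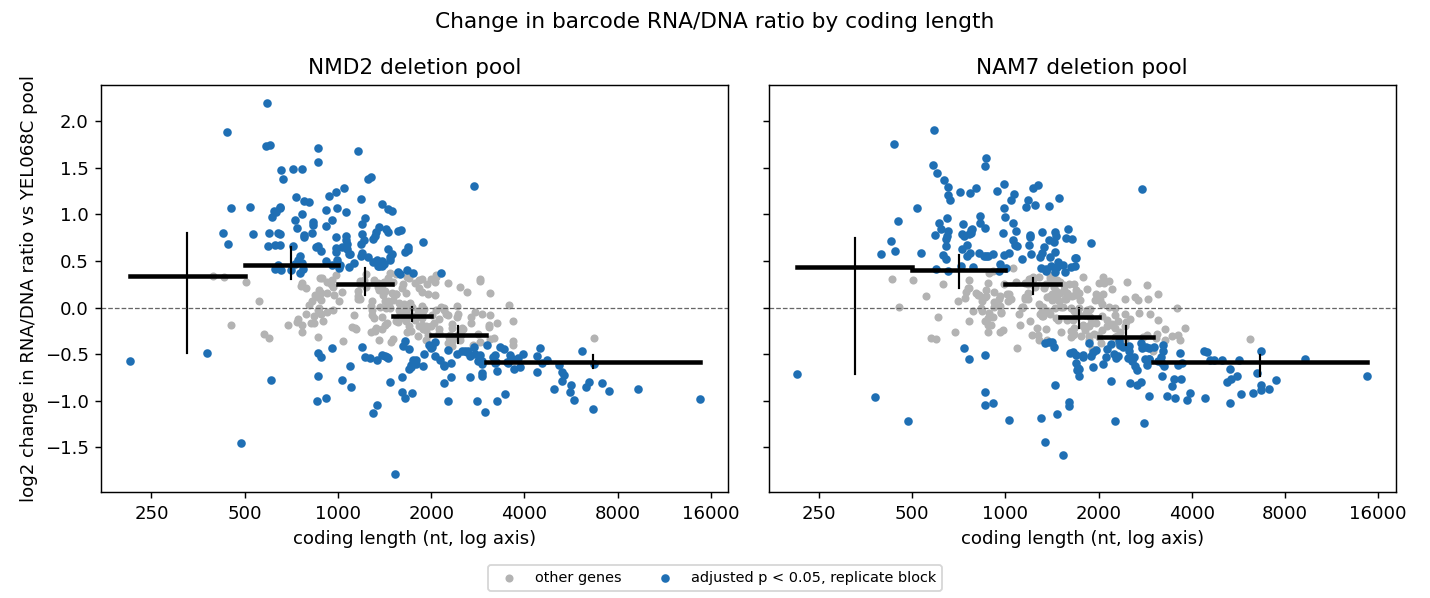
Log2 change in RNA/DNA ratio against the YEL068C pool (vertical axis) by coding length in nucleotides (horizontal log axis), 1 point per gene, for the NMD2 pool and the NAM7 pool; thick lines are class medians, thin vertical lines their 95% bootstrap intervals, and blue points pass with the replicate block. The class medians fall from 0.46 in the class up to 1000 nucleotides to -0.58 over 3000 in the NMD2 pool and from 0.40 to -0.58 in the NAM7 pool.

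Gene lists moved in both directions in the mean of both mutant pools. Genes of lipid, sterol and glycan synthesis were higher, with a median of 0.37 over 38 measured genes (adjusted p = 0.014 in camera, adjusted p = 0.44 with an estimated correlation). With the block 22 of them rose, 5 fell and 11 did not pass, DPM1 (1.21) and PIS1 (1.26) beside ERG1 and PMI40 among the increases and OLE1 among the decreases. Genes of mitochondrial import, heme and iron-sulfur cluster synthesis had a median of 0.60 over 12 genes (adjusted p = 0.0172, adjusted p = 0.44 with an estimated correlation). With the block 8 rose, YAH1, PAM16 (1.0) and HEM13 (0.92) among them, and 0 fell. Ribosome biogenesis genes were lower, with a median of -0.25 over 56 genes (adjusted p = 0.0137, adjusted p = 0.44 with an estimated correlation). With the block 26 fell, such as MDN1, UTP20, SOF1 (-0.97) and UTP10 (-0.91), while 7 rose, such as ESF1 (0.70). DPM1, PIS1, PAM16, HEM13, SOF1, UTP10 and ESF1 lie outside the rule for named genes and were chosen after their values were seen. Adjusted over the list alone without the block, 6 lipid and glycan genes passed, 2 mitochondrial genes and 0 ribosome biogenesis genes, against 3, 1 and 0 over all genes. By fry only the mitochondrial list passed (adjusted p = 0.0175). Lipid and glycan genes (adjusted p = 0.137 in fry) and ribosome biogenesis genes (0.052) did not. The medians in arrays numbered 1 and 2 were 0.29 and 0.47 for lipid and glycan genes, 0.59 and 0.61 for mitochondrial genes and -0.28 and -0.29 for ribosome biogenesis genes. RNA polymerase genes passed in the NMD2 pool (median -0.52, adjusted p = 0.0438, adjusted p = 0.384 with an estimated correlation) and missed the threshold in the mean (adjusted p = 0.076). Their NMD2 call was lost without centring and when YEL068C replicate 2 or either NMD2 array was left out. In the mean, with the block, 9 of 11 fell, RPC17 most, and RPB5 (0.72) and RPC40 (0.43), both outside the rule, rose. Abundant mRNAs had a median of 0.66 over 15 genes, which passed with the block (adjusted p = 0.0344, adjusted p = 0.523 with the block and an estimated correlation). Without the block they did not pass (adjusted p = 0.157, adjusted p = 0.784 with an estimated correlation), except when YEL068C replicate 2 or NAM7 replicate 1 was left out. No list passed in the mean when YEL068C replicate 1 was left out, and lipid and glycan genes did not pass without NAM7 replicate 2.

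The other lists did not pass in the mean, and their blocked gene counts are given here. Chromosome segregation genes counted 4 higher and 12 lower of 22, BRN1 among the lower, and DNA replication genes 5 higher and 10 lower of 26, with POL30 and POL2 on opposite sides. Aminoacyl-tRNA synthetase genes counted 5 higher and 2 lower of 12, with TYS1 higher, and translation factor genes 1 higher and 3 lower of 7, with SUI3 lower. Nuclear transport genes counted 3 higher, SRM1 (0.94) and RNA1 (1.12) of the Ran cycle among them, and 4 lower of 15. Secretory pathway genes counted 6 higher, such as SEC17 (1.02) and BET4 (0.68), and 6 lower of 26. Splicing genes counted 5 higher, such as AAR2 (0.92), and 5 lower of 19, such as BRR2 (-0.75), and transcription initiation genes 4 higher, such as SSL1 (0.61), and 5 lower of 20, such as MOT1 (-0.82). Proteasome genes counted 2 higher, RPT1 (0.46) and PRE7 (0.55), and 3 lower of 17, and the genes of the exosome and 3'-end processing 2 higher, PTI1 among them, and 4 lower of 11. Only 4 chaperonin-related genes were measured, of which SIS1 differed by 0.60 (blocked adjusted p = 0.0036 in limma) and CNS1 by 0.18 (0.268). The others, outside the rule for named genes, were TCP1 at 0.53 (blocked adjusted p = 0.0036 in limma) and CCT2 at -0.09 (0.519). The 1 ribosomal protein gene measured, RPL17A, was at -0.82 (adjusted p = 0.635 in limma, 0.000397 with the block). Without YEL068C replicate 1 the RPL17A difference was 0.14.

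The changes in the NMD2 and NAM7 pools were close to each other gene by gene. With the block 105 genes were higher and 88 lower in both pools, and 0 genes passed in opposite directions. Independent lists would share 32.4 and 28.2, values that leave out the YEL068C arrays used in both comparisons and so are not what unchanged pools would give. Across 444 features Pearson's r was 0.94 and Spearman's rho 0.93, where unchanged pools sharing the YEL068C arrays gave a mean r of 0.50 and rho of 0.47 in simulation, and 89.4% of features changed in the same direction against 66.7% simulated. The covariance was 0.337, against 0.0716 simulated with the spread of the fit without the block and 0.0112 with that of the blocked fit. With NMD2 taken from one set of same-numbered arrays and NAM7 from the other, so that no array was shared, r was 0.81 and 0.87 and the covariance 0.314 and 0.33. Both YEL068C arrays still came from 1 pool.

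**Figure D3:**
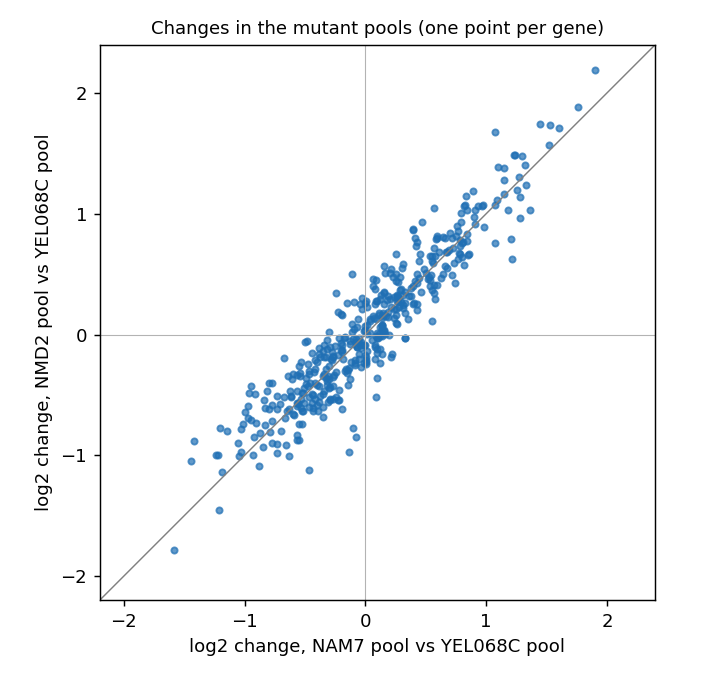
Log2 change of each of 444 features in the NMD2 pool (vertical axis) against the NAM7 pool (horizontal axis), both relative to the YEL068C pool; the diagonal marks equal changes. The points lie along the diagonal with r = 0.94, and both axes share the 2 YEL068C arrays.

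A direct comparison of the mutant pools asks whether loss of the 2 factors acts alike. By limma 0 genes passed between NMD2 and NAM7 without the block (2 at an unadjusted p under 0.05) and 0 with it (55, smallest adjusted p = 0.0562). The smallest p-values belonged to RCL1 (-0.78, SE 0.27) and MIF2 (-0.84, SE 0.34), both lower in the NMD2 pool. Then came NSE3 (0.61), NNF1 (-0.68), DYS1 (0.60), CDC14 (0.43), AAR2 (-0.59), NUP145 (0.42), DHR2 (-0.43) and DBP10 (-0.66), none of which passed. Of these, DYS1 lies within 100 kb of the deleted NMD2. Ribosome biogenesis genes as a list were lower in the NMD2 pool than in the NAM7 pool, with a median of -0.12 over 56 genes, 41 of them below 0 (adjusted p = 0.00386 in camera, adjusted p = 0.379 with an estimated correlation). They did not pass when NAM7 replicate 1 or NMD2 replicate 2 was left out. Across genes, the difference between the pools had a rho of -0.03 with coding length, which did not pass (permutation p = 0.579). Leaving out one array under the block gave 0 to 5 genes, 3 without either YEL068C array and 5 without NAM7 replicate 2.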

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

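The tests of the direction of the list difference within each array set and of coding length among the missing genes were chosen after the results had been seen. Ribosome biogenesis genes drew attention because the direct test between mutant pools passed for them (adjusted p = 0.00386 in camera), with a median of -0.121 in the NMD2 pool relative to the NAM7 pool. The call was lost with an estimated correlation (adjusted p = 0.379) and when NAM7 replicate 1 or NMD2 replicate 2 was left out. By fry, which tests the list against no change rather than against other genes, it did not pass (adjusted p = 0.947). The median was -0.18 in arrays numbered 1 (39 of 56 genes below 0), where that of all genes was -0.015, and -0.065 in arrays numbered 2 (38 of 56), where that of all genes was 0.075.

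A signal also appeared outside the compared genes. There were 30 genes with values on all 4 mutant arrays and on neither YEL068C array, against 4 missing in the same way from the NAM7 pool and 4 from the NMD2 pool. They include the chaperonin genes CCT4 and CCT7, the initiation factor genes TIF34, TIF35 and GCD11, the ribosome assembly gene TIF6 (3.18 in the mutant pools), the RNA polymerase genes RPB3, RPB7, RPC19 and RPC34, the translocon gene SEC61 (2.11) and the mitochondrial import gene TIM17 (2.20), chosen after their values were seen. Linkage to the deleted YEL068C locus is argued against, since 0% of them lie within 100 kb of it. A low ratio shared by all pools is argued against too, since their median of 0.685 in the mutant pools lies inside the -0.50 to 0.81 of random gene sets. An extreme ratio in the YEL068C pool alone stays open, since these genes have no value there. Their median coding length was 849 nucleotides, below the 1081.5 to 1758 of random sets of 30 genes, so their absence from the YEL068C pool may be related to short coding length. Strain loss in the 1 YEL068C cross and the authors' filtering stay open, as the filter is not given in the sources used here.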

How the results depend on the processing

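The fits with the block and an array left out, the block with an estimated correlation, the same-numbered sets and the pairs with no shared array were added after seeing the data. The length trend kept direction and threshold under each alternative run for it. With 1 array left out, its rho for the mean ranged from -0.672 to -0.412. The trend was not run with genes valued on at least 1 array per pool, and the block cannot move it in this balanced design. The NMD2 and NAM7 correlation was run only with an array or the genes near a deleted locus left out, and with no shared array. It kept direction in each, and threshold where a threshold applied. Counts of changed genes depended on the replicate block, with 239 (NMD2), 225 (NAM7) and 266 (mean) against 0, 0 and 18, because the block takes up the spread between replicate numbers. Keeping genes whose 2 arrays differ by at most 1 in every pool gave 49, 50 and 85, a filter on the spread that the test itself uses. The mean count was 0 without centring and 0 with values on at least 1 array per pool. It was 17 without the genes within 100 kb of a deleted locus, such as DYS1. Leaving out 1 array gave 0 to 7 (NMD2) and 0 to 9 (mean), and with the block 124 to 235 (NMD2) and 0 to 5 (NMD2 against NAM7); the lone array is assumed to vary like the others, and fewer arrays raise the error. By fry 1, 1, 1 and 0 lists passed (NMD2, NAM7, mean, NMD2 against NAM7), the mitochondrial list each time. Fry tests against no change rather than against other genes. Lists called by camera fell from 4, 3, 3 and 1 in this order to 0 in each with an estimated correlation, with or without the block. They ranged from 0 to 5 (NAM7), 0 to 4 (mean) and 0 to 2 (NMD2 against NAM7) with 1 array left out. Without the block, the estimated correlation was 0.00337 for ribosome biogenesis, -0.00235 for RNA polymerase, 0.0123 for mitochondrial and 0.0726 for lipid and glycan genes. The preset was 0.01. For ribosome biogenesis and RNA polymerase genes the estimate lay below the preset, which argues against co-movement of their genes as the cause of that loss. For these lists the preset and estimated settings therefore differ in more than the correlation. Their loss under the estimated setting does not show that their genes move together. Except where a cause is given, the cause was not tested. Genes uncalled without the block turned sign, GPI15 (-0.11) and PRI2 (-0.067) under quantile normalization. With 1 array left out, the changes of RPL17A, CDC19, FAD1 and GPI15 ranged from -1.78 to 0.138, -0.32 to 0.865, -0.27 to 0.595 and -0.22 to 0.985, in this order. With the block RPL17A (adjusted p = 0.000397 in limma) and GPI15 (0.0344) passed. The block changed 1 list call per comparison with YEL068C, that of the abundant mRNAs, and no other. All tags of a gene as an alternative was not run, because tags could not be told apart. Signal over background was not analysed here.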

Other observations

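Ratios in the YEL068C pool differed between gene groups in ways the comparisons above leave out. The test of level was planned for the lists of abundant mRNAs and ribosomal proteins. The groups given here were singled out after their levels had been seen. Aminoacyl-tRNA synthetase genes (median 2.13, 12 of 12 above the array median), translation factor genes (2.12, 7 of 7), RNA polymerase genes (1.46, 11 of 11), proteasome genes (1.09, 17 of 17) and ribosome biogenesis genes (0.95, 49 of 56) lay high, with adjusted permutation p of 8.5e-05, 0.00298, 0.00695, 0.00929 and 0.000113. Chromosome segregation genes (-1.19, 2 of 22 above), DNA replication genes (-1.09, 3 of 26) and splicing genes (-1.07, 2 of 19) lay low, with adjusted permutation p of 0.00422, 0.00456 and 0.0185. Transcription initiation genes (-0.73, 5 of 20 above) did not pass (adjusted permutation p = 0.128). The list that set the direction of the ratio shares 3 of its measured genes with the synthetase list and 1 with the translation factor list. With the other direction, the groups given as high would be low and the reverse.

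Some genes ran against the length trend, and they were chosen after their values were seen. With the replicate block, 12 of the 77 genes up to 1000 nucleotides that passed were lower in the mutant pools, RPC17, SUI3 and SUI2 (-1.0), RPL17A, MCM1 (-0.50) and the proteasome genes PRE6 (-0.41) and PRE1 (-0.34) among them. Of the 87 passing genes over 2000 nucleotides, 2 were higher, PMA1 of the plasma membrane proton pump (1.29) and GFA1 of chitin precursor synthesis (0.33).

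The tests on ratio level, on the YEL068C pool and on loss of decay for the length trend were chosen after the trend had been seen. A compression of the ratio by level is argued against, since the correlation with coding length at a held YEL068C level stayed at -0.414 or stronger, and a fault of one array run is argued against by -0.572 or stronger in both sets. Loss of either decay factor is consistent with the trend, which was -0.592 or stronger in both pools, as a hypothesis from the same data. Technical variation that follows coding length stays open, because the difference between arrays of a pool correlated with length at up to -0.289, between the bounds set in advance. A property of the 1 YEL068C pool cannot be told apart from loss of decay, since no other reference pool was compared and both mutant pools share it (their difference had rho = -0.027).

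The list shifts could follow from the coding length of their members. Of the 3 lists called in the mean, 2 lay outside the central 95% of random lists matched on length class: lipid and glycan genes (0.37 against -0.11 to 0.25) and ribosome biogenesis genes (-0.25 against -0.23 to 0.04). The mitochondrial list lay inside (0.60 against -0.05 to 0.66), so for it length alone may be enough. The explanation also stays open for ribosome biogenesis genes in the NAM7 pool alone (-0.18 inside a matched range of -0.24 to 0.05) and for RNA polymerase genes in the NMD2 pool (-0.52 inside -0.575 to 0.155). Of the lists not called in the mean without the block, those of abundant mRNAs (0.66 against -0.23 to 0.285), synthetase genes (0.245 against -0.44 to 0.09), secretory pathway genes (0.12 against -0.33 to 0.09) and chromosome segregation genes (-0.42 against -0.28 to 0.22) lay outside their ranges. The random lists draw genes independently, whereas abundant mRNAs, synthetase genes and lipid and glycan genes had estimated inter-gene correlations of 0.446, 0.305 and 0.0726. Their ranges may therefore be too narrow, and no adjustment was made for the number of lists.

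The orientation of the downstream neighbour was tested as a hypothesis of its own, since an extended mRNA could meet a convergent gene. The median change of 248 genes with a convergent neighbour differed by 0.006 from that of 185 genes with a tandem one (permutation p = 0.952), under the bound of 0.1 set in advance, which argues against a role of orientation in the change.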
